A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

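RNA of budding yeast was measured on two-colour Agilent arrays (design 015984) in 6 samples, of which 5 had scanner files for 11 arrays: nup157Δ (2), nup170Δ (3) and nup188Δ (2) against wild type, and Sth1p depletion (2) and reinduction (2) against 0 h. Per the labels the nup strains grew in rich medium and the Sth1p strain in synthetic medium without methionine, to which methionine was added for 2 h or for 8 h and then removed for 4 h. Each array was taken as 1 replicate, because the labels state duplicate experimental and technical replicates without saying which array is which. The labels give the nup157Δ and nup170Δ strains and their lys2Δ wild type as MATa, and the nup188Δ strain as MATα against a MATa wild type lacking MET15.

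For 8 arrays the scanner files hold Agilent Feature Extraction 10.7.3.1 output, and per the file headers its signals and backgrounds are intensity values and its ratios are log10. The nup170Δ arrays were deposited as output of a scanner program that their files do not name, with intensity values at high and low gain for Alexa647 and Alexa555 and the share of saturated pixels of a spot in percent. Their spots carry no probe names, and 13048 of 13048 features matched the Agilent layout by grid position. The authors' deposited tables, one per comparison, hold mean intensity per channel, a log10 ratio, a signed fold as a score, the score lambda (a likelihood ratio statistic), and as other unit the number of replicate spots kept. The series' deposited value table is the authors' signed fold on the log2 scale, rounded to 1 decimal. The program that made the authors' tables is not stated in the files.

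Red over green was used as experimental over control on every array, for the reasons given with the first signed values. For nup170Δ, the 2 gains were combined by replacing saturated high-gain spots (between 15.8% and 41.8% of spots per array and channel) with the low-gain signal times the fitted factor (11.1 to 13.8). Background was subtracted with limma's normexp (offset 50), ratios were normalized within each array by loess, and the 2 spots of each of 6256 probes were averaged. A probe was kept when well above background in at least 1 channel on every array of at least 1 group, by the Agilent flags or, for nup170Δ, by 2 background SDs. This left 6225 genes (6222 with a value for nup188Δ). Each systematic name has 1 probe, and 5756 of 6256 names are in the reference annotation, which came without coordinates, so distance is counted in ORFs by systematic name.

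One limma fit over the 11 arrays had a mean per group (6 residual degrees of freedom, 5.63 prior), with eBayes and an intensity trend, and Benjamini-Hochberg adjusted p under 0.05 was the threshold. Differences between groups were tested as contrasts of the same fit. Arrays of a group lay on 1 slide, with nup157Δ and nup188Δ together on 1 slide, both Sth1p groups on another and nup170Δ on its own. Median signals per channel lay between 19475 and 35022 for nup170Δ and between 656 and 2575 on the other arrays except reinduction array 2 (213 and 194). Signal over background limits which genes can be measured, and the number of arrays limits the precision of each fold. The median SD between arrays of a group was 0.12 for nup157Δ, 0.09 for nup170Δ, 0.15 for nup188Δ, 0.10 for depletion and 0.10 for reinduction. At the same spread, a median SD from 2 arrays runs lower than one from 3. The nup170Δ value therefore cannot be set directly beside the others.

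The 36 gene lists, fixed before the data were examined, were ribosomal proteins, ribosome biogenesis, outermost ORFs, Y′ helicases, seripauperins, the COS family, silencing factors, RSC subunits, nucleoporins, karyopherins, core histones, genes of methionine and sulfur, arginine, lysine, histidine with branched chain and aromatic amino acids, and purines, stress and heat genes, trehalose and glycogen, oxidative phosphorylation, the mitochondrial genome, hexose transport, glycolysis, the phosphate, iron and zinc regulons, ergosterol, G1/S and G2/M genes, the proteasome, a-specific, alpha-specific and haploid genes, meiosis, cell wall integrity, vitamins B1 and B6, and strain markers. They were tested with camera at a correlation between genes of 0.01, and again with the correlation estimated and with fry. The comparisons, tests, filters and most alternatives were also set before the data were examined. So was the rule for naming genes: the deleted or regulated gene and strain markers, the 8 highest and 8 lowest called genes with the same sign on every array, up to 4 members with the smallest p per called list, and the 5 largest each way per tested difference. For methionine the rule took the 8 highest and 8 lowest of the authors' deposited table among genes measured on every spot, and the methionine list. All 6256 genes met that condition, so it removed none and set no lower limit on signal. The text prints a selection of the list members so chosen.

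The fit was tested on simulated data of 6225 genes, with 200 changed by a set fold in each group. The outermost ORFs and a further gene list were also raised in every group, and calls of them count as true. The shares of false calls therefore refer to more than 200 changed genes. With equal spread, between 4.05% and 5.39% of calls were false, and with each group's own spread 7.59% for nup157Δ, 2.39% for nup170Δ, 23.2% for nup188Δ, 2.74% for depletion and 2.67% for reinduction. Each group's own spread was scaled by the median SDs above, with no correction for the number of arrays. Over both kinds of spread, between 74.6% and 91.0% of genes changed 1.5-fold were called, and 100% of those changed 4-fold. Versions were R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

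Alternatives set beforehand were no background subtraction, the scanner software's processed values, median centring in place of loess, scaling between arrays, no filter, a filter on both channels of every array, no intensity trend, groups fitted alone, a 1.5-fold minimum, the other list tests, leaving out each array, and the authors' deposited tables. Alternatives added after the data were seen were array weights, the low-gain scan alone for nup170Δ, 4 and 16 outermost ORFs, a block on the array number, and distance without the YRF1, PAU and COS families. For the nup170Δ arrays the processed values were the combined signals less background, median centred without loess. Wild type cells with and without methionine had no scanner file, so only the authors' deposited table was used for them.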

Results

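The study measured messenger RNA in budding yeast strains lacking 1 of 3 nucleoporins, the proteins that build the nuclear pore, and in a strain in which the chromatin remodeller Sth1p could be switched off. Sth1p is the ATPase of the RSC complex, and its gene was placed behind the MET3 promoter, which methionine represses. Each array carried a control RNA and an experimental RNA in different dyes. There were 2 arrays of nup157Δ against wild type, 3 of nup170Δ against wild type and 2 of nup188Δ against wild type, all from cells grown in rich medium. A further 2 arrays set 2 h of Sth1p depletion in methionine against 0 h, and 2 set reinduction, 4 h without methionine after 8 h with it, against 0 h. A comparison of wild type cells with and without methionine was used only through the authors' deposited table. Every array held 2 spots for each of 6256 probes. On 10 of the 11 arrays the share of spots above background lay between 91.2% and 99.1% in either channel, but on reinduction array 2 it was 17.4% for the experimental RNA and 30.6% for the control RNA. The number of arrays, 2 or 3 per comparison, limits the precision of every value. The labels do not say whether the arrays of a comparison came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

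All ratios are given as experimental over control RNA. The labels assign Cy5 to the control and Cy3 to the experimental RNA, whereas in the scanner values the red channel behaved as the experimental RNA on the deletion and depletion arrays. In the red channel of each deletion comparison the deleted gene was low, and in the depletion arrays STH1 was low there. The sign of the authors' deposited table ran the same way, and the direction rests on these facts rather than on the dye labels. No dyes were swapped, so a dye bias of a single probe stays in its ratio. Values are log2 ratios ± the standard error of the model, and a gene changed when its limma adjusted p passed the threshold of 0.05 over 6225 genes tested. For each gene list, the counts over all genes are followed, in square brackets, by those adjusted over the list alone. A list moved when camera's adjusted p passed the threshold over all lists. A further adjusted p, with an estimated correlation between genes, is given beside it. Under it 0 of the 75 camera calls over 180 pairs of list and comparison held (24 pairs at an unadjusted p). By fry 71 of the 180 pairs passed, and 52 of the 75 camera calls held. Genes named as highest or lowest had the same sign on every array of their comparison.

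Loss of Nup157p was compared with wild type to ask how a nucleoporin related to Nup170p affects expression. NUP157 itself was 17-fold lower in nup157Δ cells (log2 -4.09 ± 0.11, n = 2 arrays). The strain markers followed the genotypes: URA3 was 3.08 ± 0.24 and LYS2, which the control strain lacks, was higher on 2 of 2 arrays. The amount cannot be given for LYS2, because its control signal was above background on 1 of 2 arrays. URA3 and LYS2 differed along with NUP157, so effects of markers and deletion on other genes cannot be told apart. Among other genes the largest falls were in URA1, a pyrimidine synthesis enzyme (6.94-fold, -2.80 ± 0.10), and MDH2, the cytosolic malate dehydrogenase (5.57-fold, -2.48 ± 0.12). The weak acid exporter PDR12 (-1.66 ± 0.18), the riboflavin enzyme RIB4 (-1.55 ± 0.11), the transporter AQR1 (-1.51 ± 0.12), the transcription factor ADR1 (-1.36 ± 0.11) and the ferric reductase FRE4 (-1.17 ± 0.19) also fell. RGI1, a gene of respiratory growth, rose (1.29 ± 0.28), as did the peptide transporter PTR2 (1.21 ± 0.17), the repressor NRG2 (1.17 ± 0.15), the proteasome subunit PRE6 (1.01 ± 0.17) and the cell wall mannoprotein TIR1 (0.98 ± 0.20). MAM1 rose too (1.22 ± 0.17), and it is the ORF next to the deleted NUP157. Across the genome 948 of 6225 genes changed, 514 higher and 434 lower, and 146 of them by at least 1.5-fold (98 higher, 48 lower). Without array 1 the count was 17 (7 higher, 10 lower) and FRE4 (-1.19), RGI1 (0.80), MAM1 (1.37), PTR2 (0.94), NRG2 (0.91), PRE6 (0.65) and TIR1 (0.58) were not called. The count was 554 without array 2 and 605 or 538 without nup170Δ array 1 or 2, which share the estimate of spread.

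Genes of arginine, histidine and purine synthesis fell in nup157Δ cells, whereas the lysine list (0.13) was not called. The arginine list had a median of -0.32 (6 lower and 0 higher of 9 [6 and 0]), with ARG1 at -0.99 ± 0.17 and CPA1 at -0.68 ± 0.11. The list of histidine, branched chain and aromatic amino acid genes had a median of -0.26 (14 lower and 0 higher of 33 [15 and 1]), led by ILV2 (-0.56 ± 0.09) and LEU4 (-0.59 ± 0.10). Purine synthesis genes had a median of -0.35 (7 lower and 0 higher of 16 [8 and 0]), with GUA1 at -0.51 ± 0.12 and ADE4 at -0.55 ± 0.13. Methionine and sulfur genes had a median of -0.11 (5 lower and 1 higher of 38 [8 and 1]), with MET6, methionine synthase, at -0.83 ± 0.14. Karyopherins, the transport receptors that pass through the pore, had a median of -0.28 (7 lower and 0 higher of 15 [10 and 0]), with KAP122 at -0.52 ± 0.11 and KAP95 at -0.49 ± 0.11. Glycolysis fell as well (-0.19, 4 lower and 1 higher of 24 [4 and 1]), with HXK2 at -0.61 ± 0.11. The iron regulon was at -0.18 (3 lower and 0 higher of 30 [3 and 0]) and the zinc regulon at -0.23 (3 lower and 0 higher of 15 [6 and 0]), with IZH2 at -0.48 ± 0.12. Cell wall integrity genes were at -0.16 (6 lower and 1 higher of 29 [6 and 1]), with SUN4 at -0.61 ± 0.11. Ribosomal protein genes rose by 0.10 (15 higher and 1 lower of 137 [7 and 0]) and seripauperins by 0.15 (1 higher and 0 lower of 24 [1 and 0]). Small upward shifts were also seen in silencing factors 0.15 (8 higher and 0 lower of 30 [10 and 1]), RSC subunits 0.06 (5 higher and 0 lower of 17 [5 and 0]) and the proteasome 0.22 (5 higher and 0 lower of 34 [5 and 0]). ESC1, which tethers silent chromatin to the nuclear envelope, was at 0.63 ± 0.09, the RSC subunit LDB7 at 0.74 ± 0.09 and RPL24B at 0.79 ± 0.14. These 14 of 36 lists passed camera (adjusted p 1.1e-05 for the histidine list, lower on 2 of 2 arrays), with adjusted p 0.308 to 0.831 with an estimated correlation. Without array 1 none of the list members named in this paragraph was called, with ARG1 at -0.96, CPA1 at -0.56, ILV2 at -0.47, LEU4 at -0.53, GUA1 at -0.43, ADE4 at -0.27 and MET6 at -0.67. KAP122 then stood at -0.44, KAP95 at -0.30, HXK2 at -0.68, IZH2 at -0.35, SUN4 at -0.45, ESC1 at 0.68, LDB7 at 0.63 and RPL24B at 0.64. Without array 2 neither GUA1 (-0.58) nor HXK2 (-0.54) was. Without array 1 the list calls of ribosomal proteins (median -0.00), seripauperins (0.07), purine genes (-0.13), the proteasome (0.07) and cell wall genes (-0.12) ended, and without array 2 those of RSC (-0.02), glycolysis (-0.12) and iron (-0.09). The RSC call also ended without nup188Δ array 1 (0.06) and the iron call without reinduction array 1 (-0.18). The glycolysis call ended under median centring in place of loess (-0.15), and the RSC call in the scanner software's processed values (0.07). Among genes well above background in both channels on every array, the calls of karyopherins (-0.28) and iron genes (-0.25) ended. By fry those of ribosomal proteins, seripauperins, methionine, iron, proteasome and cell wall genes ended.

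Deletion of NUP170, the nucleoporin named in the study's title, was measured on 3 arrays. NUP170 fell by 6.55 on the log2 scale (SE 0.10, n = 3 arrays) and stood above background in nup170Δ cells on 1 of 3 arrays. MET17, the gene the labels call MET15 and the mutant strain lacks, was at -7.08 ± 0.22. LYS2 was at least 25.5-fold higher, a bound because the lys2Δ control was not well above background on any array. Both markers differed along with NUP170, so effects of markers and deletion on other genes cannot be told apart. Genes of the chromosome ends rose: the Y′ helicase copies had a median of 2.33 (8 higher and 0 lower of 8 [8 and 0]), led by YRF1-7 (2.49 ± 0.13) and YRF1-3 (2.44 ± 0.15), with YPR204W (2.45 ± 0.14) and YLL067C (2.42 ± 0.13), further Y′ ORFs, beside them. These copies are nearly identical in sequence, so their probes cannot assign the signal to 1 locus. The ORFs counted as outermost, the 8 nearest each chromosome end, had a median of 0.39 (150 higher and 36 lower of 252 [153 and 38]). The subtelomeric COS family was at 0.58 (7 higher and 1 lower of 12 [8 and 2]), with COS12 at 1.88 ± 0.12 and COS1 at 1.16 ± 0.10. The seripauperins were at 0.35 (15 higher and 0 lower of 24 [15 and 0]), and in both families close members cannot be told apart. By rank from the chromosome end the shift was largest at the tip. ORFs 1 to 4 had a median of 0.73 (95 higher and 9 lower of 125) and ORFs 5 to 8 of 0.14 (55 and 27 of 127). ORFs 9 to 16 had a median of 0.04 (76 and 67 of 256) and all others of -0.01 (1375 and 1581 of 5504). The bins include ORFs of Y′ elements, 42 of the 252 outermost ORFs with a median of 2.22, and were not computed without them.

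Ribosomal protein genes rose in nup170Δ cells with a median of 0.73 (123 higher and 6 lower of 137 [124 and 7]), among them RPL31A (1.55 ± 0.09) and RPL36B (1.57 ± 0.09). Genes of oxidative phosphorylation (0.59, 37 higher and 5 lower of 49 [37 and 6]) and of the mitochondrial genome (0.59, 13 higher and 2 lower of 22 [13 and 2]) rose too. Among them were QCR7 at 1.71 ± 0.14, QCR6 at 1.20 ± 0.08 and ATP6 at 1.98 ± 0.13. Hexose and maltose transport and use (0.48, 17 higher and 6 lower of 29 [17 and 6]) included HXT7 (1.86 ± 0.19) and HXT13, at least 1.79-fold higher with a control not well above background. All 7 genes expressed in a cells were higher (1.07, 7 higher and 0 lower of 7 [7 and 0]), with the a-factor gene MFA1 at 3.32 ± 0.22, ASG7 at 1.08 ± 0.12 and the pheromone receptor STE2 at 0.99 ± 0.11. ARO10, of the Ehrlich pathway, was at 2.66 ± 0.11 and NCA3 at 2.60 ± 0.09. Core histones (0.28, 5 higher and 0 lower of 8 [5 and 0]) and the proteasome (0.16, 11 higher and 1 lower of 34 [11 and 1]) rose less, with HHF1 at 0.88 ± 0.10, HHT1 at 0.97 ± 0.16 and RPN10 at 0.66 ± 0.08. The histone medians on the 3 arrays were -0.00, 0.47 and 0.62, and without array 3 the calls of histones (median 0.24) and proteasome (0.12) ended and HHT1 stood at 0.63. The adjusted p was 4.1e-24 for ribosomal proteins, 7.4e-09 for outermost ORFs and 2.5e-06 for Y′ helicases, each higher on 3 of 3 arrays, and for the 11 lists that rose adjusted p was 0.308 to 0.831 with an estimated correlation.

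Phosphate, zinc and iron genes fell in nup170Δ cells. The phosphate regulon had a median of -0.95 (19 lower and 3 higher of 22 [19 and 3]), with the secreted acid phosphatase PHO5 at 10.3-fold lower (-3.37 ± 0.10), PHO89 at -2.39 ± 0.11, PHO11 at -2.34 ± 0.08 and the vacuolar phosphatase PHO8 at -1.65 ± 0.08. PHO11 and PHO12 (-2.13 ± 0.10) are nearly identical genes. The zinc transporter ZRT1 (-2.50 ± 0.09) led the zinc regulon (-0.49, 12 lower and 0 higher of 15 [12 and 0]), and FIT3 (-2.49 ± 0.36), ARN2 (-1.91 ± 0.23) and FRE4 (-1.82 ± 0.16) the iron regulon (-0.43, 22 lower and 3 higher of 30 [22 and 3]). Purine synthesis (-0.81, 12 lower and 0 higher of 16 [12 and 0]) included ADE17 (-2.36 ± 0.16), and the arginine list (-0.40, 6 lower and 0 higher of 9 [6 and 0]) ARG1 (-2.44 ± 0.14). The histidine, branched chain and aromatic list was at -0.30 (19 lower and 5 higher of 33 [20 and 5]), with HIS4 at -1.86 ± 0.09, but at 0.01 and not called under median centring in place of loess. Glycolysis was at -0.72 (17 lower and 2 higher of 24 [17 and 3]), and likewise at 0.01 and not called under median centring, with TDH1 at -1.99 ± 0.07 and TDH2, its close relative, at -1.71 ± 0.09. The ergosterol list (-0.52, 27 lower and 3 higher of 33 [27 and 3]) held ERG3 (-1.07 ± 0.08) as well as TIR1 (-2.06 ± 0.16) and DAN1 (-1.80 ± 0.17), which are hypoxic cell wall genes. Karyopherins were at -0.32 (11 lower and 1 higher of 15 [11 and 1]), with KAP122 at -0.51 ± 0.09 and CSE1 at -0.40 ± 0.07, and the stress membrane protein HSP30 was at -2.55 ± 0.13. Adjusted p was 3.4e-08 for the phosphate list and 0.00016 for purines, each lower on 3 of 3 arrays, and the 9 falling lists had adjusted p 0.308 to 0.701 with an estimated correlation. Processed values for the nup170Δ arrays were combined signals less background, likewise median centred without loess. With them the histidine and glycolysis lists were at -0.02 each and not called. Neither were the rising COS (0.68) and proteasome lists (0.15). Among genes well above background in both channels on every array, the calls of phosphate (-0.64), iron (-0.38), karyopherin (-0.36), histone (0.28), hexose transport (0.42) and proteasome genes (0.18) ended. By fry that of the proteasome ended. In all 3418 genes changed, 1696 higher and 1722 lower, 984 of them by at least 1.5-fold (580 higher, 404 lower). Lists that did not pass included nucleoporins (-0.14, 13 lower and 2 higher of 33 [13 and 2]), silencing factors (0.05, 9 higher and 6 lower of 30 [9 and 6]), RSC subunits (0.00, 5 lower and 4 higher of 17 [5 and 4]) and methionine genes (-0.18, 17 lower and 5 higher of 38 [17 and 5]).

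**Figure D1:**
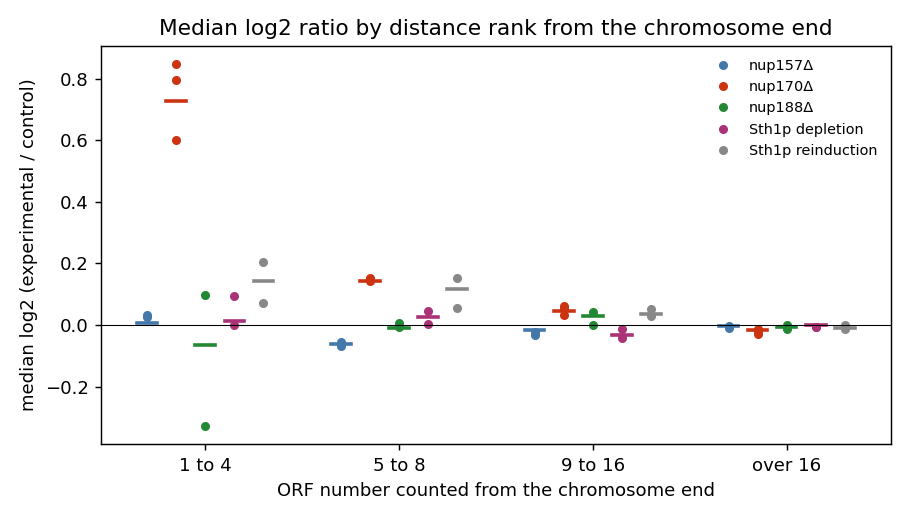
Median log2 ratio (vertical axis, experimental over control RNA) of ORFs grouped by their number counted from the chromosome end (horizontal axis, ORFs 1 to 4, 5 to 8, 9 to 16 and over 16), with 1 point per array and a short line per comparison, in 5 colours. At ORFs 1 to 4 the 3 nup170Δ arrays (0.80, 0.85 and 0.60) stand above the arrays of the other 4 comparisons, and beyond ORF 16 the nup170Δ line is at -0.01. ORFs of Y′ elements are included.

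Deletion of NUP188, a nucleoporin of the inner ring, was compared with its own wild type. NUP188 was at -5.02 ± 0.09 (n = 2 arrays), above background in nup188Δ cells on 1 of 2 arrays. LYS2, absent from the mutant strain, was at least 7.37-fold lower and MET17, absent from the control strain, was at 4.71 ± 0.27. The 2 arrays differed for MET17, at 3.84 and 5.57. Its control signal, 635 on array 1 and 87.8 on array 2, was above background on both. Both differed along with NUP188, so effects of markers and deletion on other genes cannot be told apart. The largest other falls were in YDL038C (-2.15 ± 0.28), PRM7 (-1.71 ± 0.29) and BSC1 (-2.07 ± 0.30), which are neighbouring ORFs, YDL038C being read as part of PRM7 in the current annotation. HSP30 (-1.69 ± 0.16), STP4 (-1.65 ± 0.19), the zinc transporter ZRT1 (-1.34 ± 0.11) and RGI1 (-1.49 ± 0.28) fell. YIR042C (1.45 ± 0.13) and YJL218W (1.21 ± 0.16), the chaperone genes HSP78 (1.03 ± 0.17) and STI1 (0.93 ± 0.13), the cell wall gene CWP1 (0.89 ± 0.12), the carbonic anhydrase NCE103 (0.84 ± 0.19) and COX5B (0.77 ± 0.16) rose. Over the genome 534 of 6222 genes changed, 278 higher and 256 lower, and 128 of them by at least 1.5-fold (41 higher, 87 lower). The 2 arrays correlated at 0.43 across genes, and without array 1 only 20 genes passed (4 higher, 16 lower), against 741 without array 2 and 345 or 305 without nup170Δ array 1 or 2. Array weights gave 18 genes (5 higher, 13 lower), and a fit on the 2 nup188Δ arrays alone gave 280, of which 173 were lower. In simulated data in which each group kept its own spread, 23.2% of the genes called for nup188Δ were false, against 2.39% for nup170Δ, because the fit shares 1 estimate of spread between groups. The simulated spreads were not corrected for the number of arrays, so these shares are approximate. YDL038C (then -1.74), BSC1 (-1.47), PRM7 (-1.51), STP4 (-1.45), YJL218W (1.04), HSP78 (1.00), STI1 (1.00), CWP1 (0.62), NCE103 (0.64) and COX5B (0.43) lost their calls without array 1, and RGI1 (-0.95) without array 2.

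Purine synthesis genes fell in nup188Δ cells (-0.56, 9 lower and 0 higher of 16 [13 and 0]), with SHM2 at -1.25 ± 0.15 and ADE17 at -1.29 ± 0.19. Genes of the mitochondrial genome fell as well (-0.59, 9 lower and 0 higher of 22 [16 and 0]), with COX1 at -0.76 ± 0.16 and ATP8 at -0.78 ± 0.16. Ribosome biogenesis (-0.20, 12 lower and 0 higher of 90 [31 and 3]) included DBP2 (-1.10 ± 0.22) and GAR1 (-0.66 ± 0.12). Lysine synthesis (-0.22, 4 lower and 0 higher of 10 [5 and 0]) fell with LYS2 counted among its members, and LYS20 was at -0.73 ± 0.14. Seripauperins (-0.16, 4 lower and 0 higher of 24 [6 and 0]), the zinc regulon (-0.19, 4 lower and 0 higher of 15 [5 and 0]) and karyopherins (-0.21, 1 lower and 0 higher of 15 [7 and 0]) fell less, the last with KAP104 at -0.29 ± 0.08. The proteasome rose (0.25, 5 higher and 0 lower of 34 [11 and 0]), with RPT1 at 0.51 ± 0.10. So did G1/S genes (0.17, 8 higher and 0 lower of 38 [10 and 0]), with the cohesin subunit MCD1 at 0.61 ± 0.09 and the transcription factor SWI4 at 0.61 ± 0.10. Silencing factors also rose (0.13, 4 higher and 0 lower of 30 [9 and 1]), with the histone methyltransferase gene DOT1 at 0.41 ± 0.09 and SIR1 at 0.41 ± 0.10. G2/M genes were at 0.15 (3 higher and 0 lower of 30 [3 and 0]), with HOF1 at 0.46 ± 0.09. Trehalose and glycogen genes were at 0.23 (6 higher and 1 lower of 22 [7 and 2]), with TSL1 at 0.58 ± 0.10. Stress genes (0.10, 6 higher and 3 lower of 51 [15 and 3]) and oxidative phosphorylation (0.08, 5 higher and 0 lower of 49 [5 and 0]) rose little, with IDH1 at 0.64 ± 0.10. Adjusted p was 5.5e-07 for purines and 1.2e-06 for the mitochondrial genome, each lower on 2 of 2 arrays, and the 14 lists had adjusted p 0.308 to 0.82 with an estimated correlation. Without array 1 the calls of seripauperins (median 0.01), karyopherins (-0.11), stress (0.04) and trehalose genes (0.17) ended and oxidative phosphorylation turned to -0.13, and without array 2 those of silencing factors (0.12), lysine (-0.17), stress (0.13) and zinc genes (-0.13) ended. Among the members named here, ADE17 (then -1.45), COX1 (-0.44), DBP2 (-0.65), GAR1 (-0.49), LYS20 (-0.60), RPT1 (0.44), MCD1 (0.58), HOF1 (0.40), DOT1 (0.33), SIR1 (0.25), TSL1 (0.59) and IDH1 (0.50) were not called without array 1, nor ATP8 (-0.42) without array 2. The call of KAP104 ended without either nup188Δ array (-0.26 and -0.32), any nup170Δ array or either reinduction array (-0.29 each), and those of stress (0.10) and trehalose genes (0.23) without either reinduction array. Under median centring in place of loess the calls of stress genes (0.07) and oxidative phosphorylation (0.04) ended. Among genes well above background in both channels on every array, those of G1/S (0.02), G2/M (0.16) and oxidative phosphorylation genes (0.07) ended. By fry the calls of ribosome biogenesis, seripauperins, karyopherins, stress, trehalose, oxidative phosphorylation and proteasome genes ended.

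Depletion of Sth1p for 2 h in methionine asked what follows the loss of RSC's ATPase. STH1 messenger RNA was 3.99-fold lower (log2 -1.99 ± 0.19, n = 2 arrays). Methionine and sulfur genes had the lowest median of the 36 lists at -1.74 (32 lower and 1 higher of 38 [32 and 1]). The methionine adenosyltransferases SAM1 (-3.88 ± 0.11) and SAM2 (-3.69 ± 0.10), which are close relatives, MET17 (-3.85 ± 0.27), methionine synthase MET6 (-3.83 ± 0.14), MET2 (-3.18 ± 0.13), MET3 (-3.07 ± 0.13), the methionine permease MUP1 (-2.96 ± 0.10) and MET14 (-2.89 ± 0.12) were the 8 lowest. OYE3, an NADPH oxidoreductase, rose 14.3-fold (3.84 ± 0.24), followed by the arginine enzyme ARG3 (2.48 ± 0.19), ULI1 (2.42 ± 0.17), TIR1 (2.36 ± 0.20), SIP18 (2.31 ± 0.26), ECM8 (1.99 ± 0.17) and the endoplasmic reticulum chaperone KAR2 (2.12 ± 0.11) with its nucleotide exchange factor SIL1 (2.22 ± 0.10). Depletion changed 2722 of 6225 genes, 1285 higher and 1437 lower, 943 of them by at least 1.5-fold (405 higher, 538 lower), and 1512 passed without array 2.

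G1/S genes rose on depletion (0.58, 30 higher and 1 lower of 38 [30 and 1]), with EGT2 at 1.00 ± 0.12 and the cyclin PCL1 at 0.94 ± 0.10. The proteasome rose (0.50, 24 higher and 1 lower of 34 [25 and 2]), with RPN5 at 0.92 ± 0.13 and RPN6 at 0.71 ± 0.09. The mitochondrial genome (0.45, 9 higher and 0 lower of 22 [10 and 0]) was led by AI5_BETA (1.23 ± 0.11) and COX1 (0.99 ± 0.16). G2/M genes rose less (0.19, 11 higher and 2 lower of 30 [11 and 2]), with KIN3 at 0.86 ± 0.11 and HOF1 at 0.68 ± 0.09. Meiosis genes were at 0.17 (12 higher and 5 lower of 43 [12 and 5]), with SPS4 at 1.09 ± 0.15 and SSP2 at 0.86 ± 0.08. Ribosome biogenesis was at 0.13 (23 higher and 4 lower of 90 [22 and 3]), with UTP18 at 0.67 ± 0.10. COS genes fell (-0.63, 9 lower and 0 higher of 12 [9 and 0]), with COS7 at -1.01 ± 0.11 and COS3 at -1.01 ± 0.11, in a family of closely similar members. Genes of haploid cells and the pheromone response fell (-0.42, 17 lower and 2 higher of 25 [18 and 2]), with the agglutinin anchor AGA1 at -1.89 ± 0.21 and the kinase FUS3 at -1.20 ± 0.13. Ergosterol genes fell (-0.29, 16 lower and 5 higher of 33 [17 and 6]), with squalene epoxidase ERG1 at -1.32 ± 0.08 and ERG26 at -1.23 ± 0.10. Adjusted p was 4e-17 for methionine genes, 4.9e-09 for G1/S and 7.4e-06 for the proteasome, each in its direction on 2 of 2 arrays, and the 10 lists had adjusted p 0.308 to 0.831 with an estimated correlation. Without array 1 the calls of ergosterol (median -0.24) and meiosis (0.15) ended, the latter also without nup188Δ array 2 (0.17). Under median centring in place of loess the calls of ergosterol (-0.22) and G2/M genes (0.16) ended, and in the scanner software's processed values that of meiosis (0.22). The calls of the mitochondrial genome (0.28), ergosterol (-0.26) and G2/M genes (0.19) ended among genes well above background in both channels on every array, and that of ribosome biogenesis by fry.

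Reinduction restored STH1 above its 0 h level (1.24 ± 0.19, n = 2 arrays), although without array 1 it stood at 0.82 and was not called. Time, the earlier methionine and the STH1 level all differed from 0 h, so their effects on other genes cannot be told apart. Among the lowest genes were ADE17 at -3.89 ± 0.19, the serine hydroxymethyltransferase SHM2 at -2.97 ± 0.15, the glycine cleavage genes GCV1 (-2.97 ± 0.22) and GCV2 (-2.91 ± 0.13) and ADE2 at -2.48 ± 0.15. The purine list had a median of -1.49 (13 lower and 0 higher of 16 [13 and 0]). HSP30 (-3.65 ± 0.16), ZRT1 (-2.61 ± 0.11) and RGI1 (-2.41 ± 0.28) were the others of the 8 lowest. The heat shock gene HSP26 (1.95 ± 0.24), SIP18 (1.81 ± 0.26), JLP1, a sulfonate dioxygenase (1.72 ± 0.32), the mitochondrial carrier DIC1 (1.61 ± 0.12) and the hexose transporter HXT5 (1.57 ± 0.27) rose. FIT2 (2.00 ± 0.48), FIT3 (1.62 ± 0.44) and SPG4 (1.48 ± 0.37) rose as well, but without array 1 they stood at 1.45, 1.07 and 0.31 and were not called. SIP18 (1.00), JLP1 (0.67) and HXT5 (0.70) were smaller without array 1 but still called. Of these genes SIP18, JLP1, HXT5 and SPG4 were above background on 1 of 2 arrays in both RNAs, FIT2, FIT3 and DIC1 on 1 of 2 in the control, and ADE17, HSP30, GCV1, GCV2, ADE2 and RGI1 on 1 of 2 in the reinduced RNA. In all 759 genes changed, 309 higher and 450 lower, 335 by at least 1.5-fold (132 higher, 203 lower), and without array 1 the count was 174 (48 higher, 126 lower). Without array 2, the array with few spots above background, 415 were higher and 411 lower.

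All 8 core histone genes were lower after reinduction (-0.87, 8 lower and 0 higher of 8 [8 and 0]), with HTA1 at -1.19 ± 0.13 and HTA2, nearly identical to it, at -0.96 ± 0.14. Glycolysis (-0.60, 14 lower and 1 higher of 24 [16 and 2]) fell with TDH1 at -1.75 ± 0.09. Trehalose and glycogen genes (-0.37, 10 lower and 0 higher of 22 [13 and 3]) fell with TPS2 at -0.72 ± 0.08, and the zinc regulon (-0.25, 7 lower and 0 higher of 15 [8 and 0]) with ZRT2 at -0.78 ± 0.11. G2/M genes (-0.18, 6 lower and 0 higher of 30 [10 and 1]) fell with the cyclin CLB1 at -1.38 ± 0.11, and COS genes fell (-0.23, 2 lower and 0 higher of 12 [2 and 0]). Methionine genes rose above their 0 h level (0.21, 13 higher and 6 lower of 38 [17 and 7]), with MET14 at 1.30 ± 0.12 and MET3 at 1.05 ± 0.13. The iron regulon (0.31, 9 higher and 0 lower of 30 [13 and 0]) included ARN1 (1.25 ± 0.18), and cell wall integrity genes (0.12, 10 higher and 4 lower of 29 [12 and 5]) HSP150 (1.37 ± 0.15) and PRM5 (1.16 ± 0.11). Outermost ORFs were higher as a list (0.12, 25 higher and 7 lower of 252 [25 and 7]), with DLD3 at 1.37 ± 0.13. Their median was 0.18 on array 1 and 0.06 on array 2. Higher as lists too were the next 2. These were seripauperins (0.28, 7 higher and 0 lower of 24 [9 and 0]) and Y′ helicases (0.38, 0 higher and 0 lower of 8 [0 and 0], and 4 at an unadjusted p by limma). Vitamin B1 and B6 genes (0.22, 9 higher and 0 lower of 23 [10 and 0]), meiosis genes (0.17, 6 higher and 1 lower of 43 [6 and 1]), and a-specific genes (0.47, 1 higher and 0 lower of 7 [5 and 0]) rose as well, with THI4 at 0.94 ± 0.23. None of the 7 a-specific genes was above background on array 2 in either RNA, so their rise rests on array 1. Ribosomal protein genes were at 0.09 (3 higher and 2 lower of 137 [1 and 1]), with RPP1B at 0.65 ± 0.12, but at -0.05 under median centring in place of loess. Adjusted p was 1e-17 for purines and 2.6e-08 for histones, each lower on 2 of 2 arrays, and the 17 lists had adjusted p 0.308 to 0.838 with an estimated correlation. Without array 1 the calls of COS (median -0.20), methionine (0.01), a-specific (0.10) and meiosis genes (0.06) ended, as did those of THI4 (0.26) and RPP1B (0.67) while ARN1 stood at 0.80, and without array 2 those of ribosomal proteins (0.08) and Y′ helicases (0.37). The Y′ call also ended without either nup157Δ array or depletion array 1 (0.38 each). Under median centring in place of loess the calls of Y′ helicases (0.24) and cell wall genes (0.13) ended, and in the scanner software's processed values that of COS genes (-0.26). The calls of ribosomal proteins (0.09), Y′ helicases (0.38), COS (-0.22), methionine (0.05), G2/M (-0.22) and cell wall genes (0.22) ended among genes well above background in both channels on every array. By fry those of ribosomal proteins, outermost ORFs, Y′ helicases, seripauperins, COS, methionine, iron and a-specific genes ended.

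**Figure D2:**
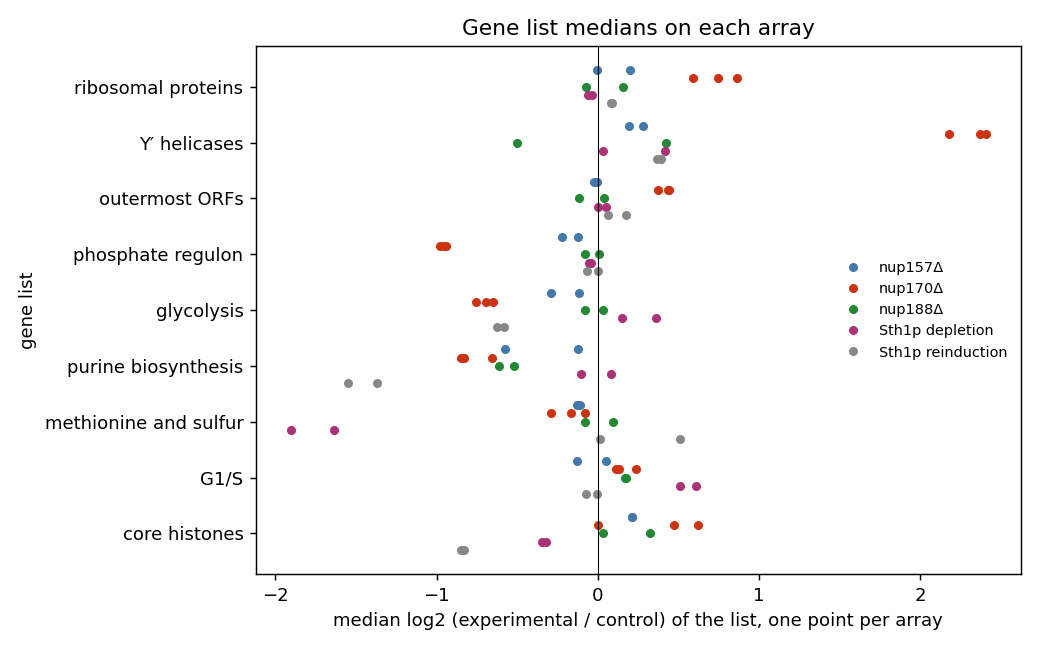
Median log2 ratio (horizontal axis, experimental over control RNA) of 9 gene lists (vertical axis), with 1 point per array, in 5 colours. The 3 nup170Δ arrays lie furthest right for Y′ helicases (2.41, 2.37 and 2.18) and ribosomal proteins (0.75, 0.59 and 0.87), the depletion arrays furthest left for methionine genes (-1.63 and -1.90) and the reinduction arrays for purine genes (-1.55 and -1.37).

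Wild type cells grown with and without methionine give the response to methionine alone, and only the authors' deposited table was used for them, with no error of its own. This table has 2 values per probe. In the authors' deposited table MET17 had a signed fold of -67.8, MIN4 of -42.8, the ATP sulfurylase gene MET3 of -32.2 and MET2 of -21.4. MET14 (-19.4), MET10 (-18.1), the sulfate permease SUL1 (-17.6) and MET16 (-11.7) completed the 8 lowest in the authors' deposited table. The 8 highest in the authors' deposited table were YOR314W (11.1), VEL1 (10.9), YOR053W (9.3), YOL106W (9.2), YDR149C (6.8), YOL079W (5.9), YAR061W (5.5) and YCR001W (5.4), most of them ORFs without a known product, and YOR053W, YOL106W, YDR149C and YOL079W are missing from the current annotation. The methionine list had a median log2 of -1.87 in the authors' deposited table, with 30 of 38 members lower by at least 1.5-fold and 1 higher, SAM4 (1.8). Purine synthesis (-0.92, 10 of 16 lower), trehalose and glycogen (-0.77, 15 of 22 lower) and stress genes (-0.68, 34 of 52 lower) were lower with methionine in the authors' deposited table. Ribosomal proteins (0.68, 85 of 137 higher) and ribosome biogenesis (0.68, 63 of 90 higher) were higher in the authors' deposited table. So were the mitochondrial genome (0.58, 13 of 23 higher) and core histones (0.63, 5 of 8 higher) in the authors' deposited table. Of these lists, ribosome biogenesis and the mitochondrial genome were also called higher on depletion. STH1 was listed at a signed fold of -1.0 in the authors' deposited table for these wild type cells. In the authors' deposited table, of all 6256 probes, 878 were at least 1.5-fold higher and 784 at least 1.5-fold lower with methionine.

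**Figure D3:**
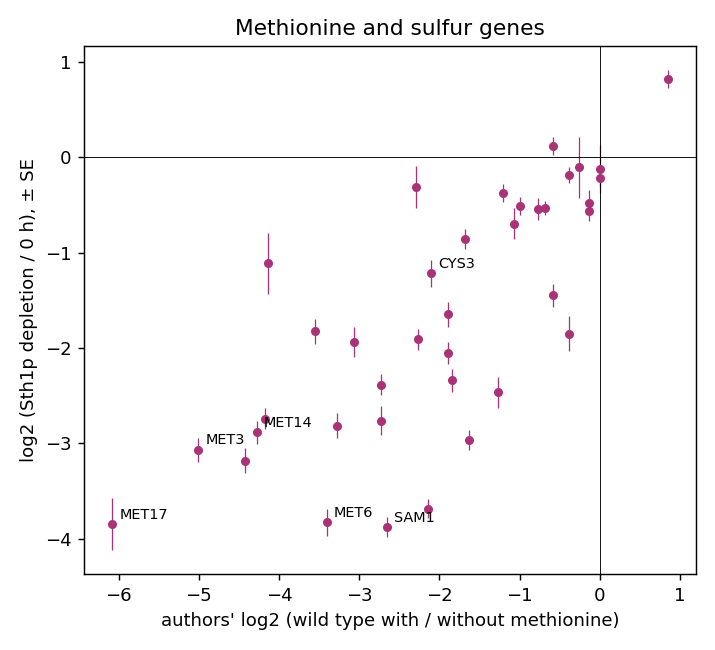
Methionine and sulfur genes, with the authors' log2 ratio of wild type cells with over without methionine on the horizontal axis and the log2 ratio of Sth1p depletion over 0 h, with its standard error over 2 arrays, on the vertical axis. SAM1 (-3.88), MET17 (-3.85) and MET6 (-3.83) lie lowest on the depletion axis.

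Phosphate and a-specific genes separated nup170Δ from nup157Δ cells when the difference itself was tested. Beyond the deleted genes and strain markers, PHO5 (-3.05 ± 0.15) and TIR1 (-3.04 ± 0.26) were lower in nup170Δ than in nup157Δ cells, and MFA1 (3.35 ± 0.35), ARO10 (2.78 ± 0.17) and NCA3 (2.76 ± 0.14) higher. TIR1 stood at -2.06 in nup170Δ and 0.98 in nup157Δ cells. The lists that were higher in nup170Δ cells included Y′ helicases (median difference 2.10), a-specific genes (0.93), ribosomal proteins (0.64), COS genes (0.61) and outermost ORFs (0.44). Lower lists included phosphate (-0.77), ergosterol (-0.48) and purine genes (-0.47). Adjusted p was 1.3e-21 for ribosomal proteins and 7.3e-09 for the phosphate list, and 0.427 and 0.105 with an estimated correlation. In all 1687 genes differed, 856 higher and 831 lower in nup170Δ. Leaving out nup157Δ array 1 left 859 and nup170Δ array 1 left 1106. The nup170Δ arrays lay on another slide and were read with another scanner program than the nup157Δ and nup188Δ arrays, so slide and deletion cannot be told apart in these differences.

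Against nup188Δ, nup170Δ cells were lower in the siderophore binding proteins FIT2 (-3.10 ± 0.62) and FIT3 (-3.08 ± 0.57) and in PHO5 (-2.91 ± 0.15). MFA1 (3.46 ± 0.35), NCA3 (2.93 ± 0.14) and ARO10 (2.75 ± 0.17) were higher, beside the strain marker MET17 (-11.79 ± 0.35). LYS2 also differed, by an amount that cannot be given because it was not above background in the nup170Δ control or in the nup188Δ mutant. Genes of the mitochondrial genome differed by 1.04, with medians of 0.59 in nup170Δ and -0.59 in nup188Δ cells. Y′ helicases (2.39), a-specific genes (0.93), ribosomal proteins (0.69) and outermost ORFs (0.48) were higher, and phosphate (-0.89), arginine (-0.76) and iron genes (-0.55) lower. Adjusted p was 1.5e-07 for the mitochondrial genome and 4.7e-10 for phosphate, and 0.244 and 0.105 with an estimated correlation. Both RNAs of the nup188Δ arrays carried the messages of α cells, in which ASG7 was above background on neither array and MFA2 and AGA2 on 1 of 2 in the mutant and 0 in the control. MFA1, STE6, STE2 and BAR1 were above background there in both RNAs on both arrays. The test called 1953 genes, 984 higher and 969 lower in nup170Δ, and 1121 without nup188Δ array 1.

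Between reinduction and depletion the methionine list differed most of the 36 lists. Methionine in the medium, time and the STH1 level all differed between these 2 states, so their effects cannot be told apart. MET17 (5.16 ± 0.39), MET14 (4.19 ± 0.17), MET3 (4.12 ± 0.18), MET10 (3.67 ± 0.15) and MET5 (3.57 ± 0.19) were higher after reinduction than after depletion. ADE17 (-3.52 ± 0.27), OYE3 (-2.98 ± 0.34), the inositol synthesis gene INO1 (-2.78 ± 0.31), ZRT1 (-2.60 ± 0.16) and ADE2 (-2.47 ± 0.21) were lower. List differences were 2.03 for methionine, 0.61 for haploid and pheromone, -1.61 for purine, -0.71 for glycolysis and -0.63 for G1/S genes. Adjusted p was 4.8e-22 for methionine and 3.6e-09 for G1/S genes, and 0.153 and 0.105 with an estimated correlation. In all 1819 genes differed, 922 higher and 897 lower after reinduction, and 1170 without depletion array 2 or 1108 without reinduction array 1. Over the 3 differences 49 of 108 list pairs passed camera, 0 of them with an estimated correlation (16 at an unadjusted p).

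Distance rank from the chromosome end, over 6012 ORFs, had Spearman coefficients across genes of 0.03 for nup157Δ, -0.08 for nup170Δ, 0.06 for nup188Δ, -0.02 for depletion and -0.09 for reinduction, where a negative value means higher ratios nearer the end. Genes are not independent replicates, so no p is given for these coefficients. For nup170Δ the 3 arrays gave -0.09, -0.09 and -0.06. Without the YRF1, PAU and COS families the 215 remaining outermost ORFs had a median of 0.40 in nup170Δ cells, 123 higher and 36 lower, but other ORFs of Y′ elements remained among them. The 210 outermost ORFs outside Y′ elements had a median of 0.29, 109 higher and 35 lower. For depletion the coefficient was 0.00 without array 2, and for nup188Δ it was 0.00 without array 1.

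Genes that fell in nup170Δ cells also fell on Sth1p depletion more often than independent lists would, 504 against 398, whereas 316 rose in both against 350. A further 325 rose in nup170Δ cells and fell on depletion, and 349 did the reverse. The log2 ratios of these comparisons correlated at 0.07 across 6225 genes, and at 0.21 under median centring in place of loess. Depletion and reinduction, both set against 0 h of the same strain, correlated at 0.26, with 114 genes higher in both against 63.8 by chance and 185 lower in both against 104. In 20 simulations of unchanged groups set against the same 0 h cultures the correlation was 0.429 and the covariance 0.0086. Both follow from an assumed share of the spread given to these cultures, so they are not a measured level without effect. Deviations of same-numbered arrays, which correlated at 0.0779, gave an estimate of 0.0016 for the covariance from shared cultures. The observed covariance was larger, at 0.0417. With 2 arrays per group the controls could not be split, so part of the excess may come from them. Depletion and the authors' deposited table for methionine correlated at 0.12 across genes. Both nup157Δ and nup170Δ were set against the same wild type strain. In both, 258 genes were higher against 140 by chance and 259 lower against 120, while 37 and 40 were called in opposite directions. The correlation was 0.28, and 0.17 under processed values, which for nup170Δ were median-centred signals without loess. The labels do not say whether the wild type cultures were the same. In 20 simulations of unchanged groups in which arrays 1 and 2 shared them, the correlation was 0.308 and the covariance 0.0031. The size of the shared part was assumed here too, so these values depend on it. The observed covariance was larger, at 0.0386. Part of this excess may likewise come from a shared control. For nup170Δ and nup188Δ the counts were 145 against 75.7 and 114 against 70.8, with 30 and 30 called in opposite directions. Their correlation was 0.11, but 0.02 without nup188Δ array 2, 0.18 without array 1 and 0.00 under processed values, so made for nup170Δ.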

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

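The tests of explanations in this part were chosen only after the result was seen, except the test of position on the array, and the tests of differences between groups were chosen beforehand.

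Differences between groups passed a test of the difference itself in the following results. Between nup170Δ and nup157Δ cells 1687 genes differed, between nup170Δ and nup188Δ cells 1953, and between reinduction and depletion 1819. For nup170Δ minus nup157Δ the median differences were 0.6449 for ribosomal proteins, 2.0970 for Y′ helicases, 0.6053 for COS genes, 0.6096 for the mitochondrial genome, -0.7724 for phosphate genes and 0.9258 for a-specific genes. For nup170Δ minus nup188Δ they were 0.6914 for ribosomal proteins, 2.3859 for Y′ helicases, -0.7565 for arginine genes, 1.0350 for the mitochondrial genome, -0.8889 for phosphate genes and 0.9276 for a-specific genes. For reinduction minus depletion they were 2.0325 for methionine genes, -1.6070 for purine genes, -0.7147 for glycolysis, -0.6297 for G1/S genes and 0.6059 for haploid and pheromone genes. With an estimated correlation none of these list differences passed by camera (adjusted p 0.105 or higher, and 16 of 108 list pairs at an unadjusted p). These counts depended on single arrays: 859 without nup157Δ array 1 and 1106 without nup170Δ array 1, 1121 without nup188Δ array 1, and 1170 or 1108 without depletion array 2 or reinduction array 1.

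ORFs near chromosome ends were higher in nup170Δ cells. A dye bias that these probes share on all arrays is argued against by the difference from nup157Δ, 0.4385, with outermost medians of 0.44, 0.44 and 0.37 on the nup170Δ arrays and between -0.12 and 0.04 on the nup157Δ and nup188Δ arrays. Signal from Y′ elements alone is argued against by the 210 outermost ORFs outside them, whose median was 0.2922 (0.31, 0.33 and 0.23 on the 3 arrays, 109 higher and 35 lower), against 2.22 for the 42 inside. Slide and scanner cannot be told apart from the deletion, because 0 nup170Δ arrays lay on a second slide. The deletion itself, the difference the design names, stays among the open explanations and was not tested apart from the slide. The mutant strain also lacks MET17, and that difference cannot be told apart from the deletion. LYS2 differed too, as it did in nup157Δ cells.

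After Sth1p depletion the methionine genes fell, and many other genes changed. Methionine in the medium may account for the methionine genes: 96.00% of those lower by at least 1.5-fold, 24 of 25, were also lower in wild type cells in the authors' deposited table. Of the other 917 genes changed by at least 1.5-fold, 16.25% (149) changed the same way in the authors' deposited table and 132 the opposite way. Of all genes outside the list, 26.1% reached 1.5-fold in the authors' deposited table. That table has 2 values per probe and no error of its own. Low agreement with it therefore cannot decide whether methionine caused these other changes. Methionine, the loss of Sth1p, the time in fresh medium and the difference in strain stay open for these other genes, and none was tested alone.

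The 2 arrays of nup157Δ and the 2 of nup188Δ disagreed. A component that same-numbered arrays of both groups share is a candidate explanation: deviations of array 1 from the group mean correlated at 0.3712 between the groups, and those of array 2, which mirror them, at 0.3699. Other than between nup157Δ and nup188Δ, deviations of arrays from different groups correlated by at most 0.2792 in either direction. Position on the array is argued against, since the difference between the nup188Δ arrays correlated at 0.9049 between the 2 spots of a probe, and that of nup157Δ at 0.828. Whether the shared component came from cultures, RNA or labelling was not tested, and no biological explanation was tested.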

How the results depend on the processing

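Array weights, the low-gain scan alone, the block on the array number, the 4 and 16 outermost ORFs and the distance without telomere families were alternatives chosen only after the results were seen, and no other tests of this part were.

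Of the values of counts and coefficients under all alternatives, 399 stayed within 1.5 times or within the spread between arrays, 60 moved and 1 reversed. Of list shifts 1457 kept their call, 170 lost it and 2 reversed by the direction of the test, and of named genes 7194 kept their side of the threshold, 377 lost the call, 66 gained it and 0 reversed. The 75 list calls all held without background subtraction and without a filter. Array weights do not enter the list test, so the calls counted as kept under them were fixed in advance. Using 4 or 16 outermost ORFs changes only the outermost list, and its calls held. With median centring 65 of the 75 calls held, with processed values 68 and with fry 52. With the filter on both channels 34 held, 20 did not and 21 lists had too few genes left.

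The filter on both channels of every array left 1313 probes, and fewer genes tested gives lower counts: 301 genes for nup157Δ, 847 for nup170Δ, 122 for nup188Δ, 505 for depletion and 275 for reinduction. Differences under it were 472 (308 higher) for nup170Δ minus nup157Δ, 533 (334 higher) for nup170Δ minus nup188Δ and 398 for reinduction minus depletion. Lists past the test under it were 8, 11 and 8 for nup157Δ, nup170Δ and nup188Δ, and 6 for reinduction. The 1.5-fold minimum gave, by its construction, 146, 984, 128, 943 and 335 genes for the 5 comparisons in the order of the report, and 905, 1006 and 1005 for the 3 differences. Log ratios scaled between arrays gave 946 genes for nup188Δ, 1626 for reinduction, and 1029 and 1100 for nup170Δ minus nup157Δ and minus nup188Δ. Processed values gave 316 genes for nup188Δ. Fits on a group's own arrays gave 280 genes for nup188Δ (173 of them lower) and 468 for reinduction, and a fit of reinduction and depletion alone gave 1168 differences. Array weights, lowest for nup188Δ (0.509), gave 18 genes for nup188Δ (5 higher, 13 lower). Estimating the correlation between genes left 0 lists called by camera in each of the 5 comparisons (4, 5, 6, 3 and 6 at an unadjusted p). For the changes under scaling, processed values, fits on own arrays and array weights the cause was not tested.

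For reinduction the coefficient with distance was -0.1133 under median centring and -0.0874 without telomere families. Processed values for nup170Δ were median-centred combined signals without loess. Under them the correlation of nup170Δ was 0.0935 with depletion, 0.1707 with nup157Δ and 0.0027 with nup188Δ. Under median centring it was 0.2089 between nup170Δ and depletion and 0.1693 between depletion and the authors' deposited table for methionine. The ribosomal protein median of reinduction reversed to -0.0492 under median centring, and the oxidative phosphorylation median of nup188Δ to -0.1263 without its array 1 (0.3634 without array 2). Among the calls lost, 5 medians also changed sign: RSC (-0.0184 without array 2) and ribosomal proteins (-0.0029 without array 1) of nup157Δ, seripauperins of nup188Δ (0.0090 without array 1), and the histidine (0.0098) and glycolysis lists (0.0072) of nup170Δ under median centring. The distance coefficient of depletion reversed to 0.0044 without its array 2. The cause was not tested for any of these.

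Leaving out each array in turn, with a lone array assumed to vary like the other groups, gave 17 to 1191 genes for nup157Δ, 2548 to 3567 for nup170Δ, 20 to 741 for nup188Δ, 1512 to 2954 for depletion and 174 to 910 for reinduction. The lowest came without array 1 of nup157Δ, nup188Δ and reinduction, without array 1 or array 2 of nup170Δ, and without array 2 of depletion. Differences ranged from 859 to 1974, from 1121 to 2012 and from 1108 to 2062. Lists past the test ranged from 13 to 15, 18 to 21, 13 to 16, 8 to 12 and 14 to 18 in the order of the report. Distance coefficients ranged from 0.0167 to 0.0329 for nup157Δ, -0.0894 to -0.0750 for nup170Δ, 0.0020 to 0.0694 for nup188Δ, -0.0389 to 0.0044 for depletion and -0.0925 to -0.0777 for reinduction. Correlations ranged from 0.0654 to 0.0801 for nup170Δ with depletion, 0.2086 to 0.2969 for depletion with reinduction, 0.1058 to 0.1227 for depletion with methionine, 0.2483 to 0.3010 for nup157Δ with nup170Δ and 0.0209 to 0.1818 for nup170Δ with nup188Δ.

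The authors' deposited tables list 580 genes at 1.5-fold or more for nup157Δ against 161 in the mean of arrays here, 1409 against 985 for nup170Δ, 688 against 160 for nup188Δ, 1703 against 949 for depletion and 941 against 371 for reinduction. In the authors' deposited tables nup157Δ and nup188Δ have 2 values per probe, and they correlate at 0.949 and 0.923 with array 1 and at 0.603 and 0.402 with array 2. The labels pair no arrays between groups, which share only an array number. A block on that number, array 1 against array 2, gave 1119 genes for nup157Δ, 3524 for nup170Δ, 707 for nup188Δ, 2849 for depletion and 873 for reinduction, and 1813, 2112 and 1968 for the 3 differences, and all 75 list calls held under it. Deviations of same-numbered arrays correlated at 0.3712 between nup157Δ and nup188Δ and at 0.0779 between depletion and reinduction. For array 1 of depletion they were 0.2102 with nup157Δ and 0.1436 with nup188Δ. For array 1 of reinduction they were 0.0622 with nup157Δ and -0.0791 with nup188Δ. A random slide block could not be fitted, since each group lay on 1 slide, and distances in kb were not run, since the annotation came without coordinates. The rule for several probes and the joint fit over array designs had nothing to change, with 1 probe per name and 1 design. The share of spots above background limited reinduction array 2 (17.4% and 30.6%) most.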

Other observations

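The genes in this part were chosen after their values were seen, except the members of the 3 lists named last.

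Probes of the silent mating loci were higher in nup170Δ cells, as were probes named for the mating type locus, and which locus gave the signal was not tested. HMLALPHA2 was at 0.83 ± 0.10, HMLALPHA1 at 0.40 ± 0.08, HMRA1 at 0.95 ± 0.07 and HMRA2 at 0.83 ± 0.10 over 3 arrays, and the probe named MATALPHA2 was at 0.90, 0.90 and 0.76 on them. These strains are labelled MATa, and close copies of a gene cannot be told apart by their probes. In nup157Δ cells HMRA1 was at 0.67 ± 0.09, HMLALPHA2 at 0.44 ± 0.12 and HMRA2 at 0.47 ± 0.12, and in nup188Δ cells HMRA1 was at 0.07 ± 0.09, HMLALPHA2 at 0.60 ± 0.12 and HMRA2 at 0.58 ± 0.12, over 2 arrays each. On depletion HMLALPHA2 was at -0.44 ± 0.12. In nup170Δ cells the a-factor gene MFA2 (1.69 ± 0.22) and the agglutinin subunit AGA2 (1.07 ± 0.16) rose, whereas STE3, the receptor by which α cells sense a-factor, was at -0.61 ± 0.10 and the endonuclease HO at -1.45 ± 0.10. Also in nup170Δ cells, the silencing factors SIR3 (-0.09 ± 0.08) and SIR4 (-0.12 ± 0.08) and the RSC ATPase STH1 (0.11 ± 0.15) were not called, while the RSC subunit RSC30 was at 1.04 ± 0.08 and its paralog RSC3 at -0.35 ± 0.06.

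The labels give the nup188Δ control as MATa, but its control channel carried the messages of α cells. MF(ALPHA)1 control signal was 22205 and 23754 on the nup188Δ arrays against 43.5 and 64.9 on the nup157Δ arrays, and STE3 was 7143 and 8237 against 86.5 and 121. The depletion strain is labelled MATa in one channel and MATα in the other, but both RNAs carried the messages of α cells. MF(ALPHA)1 signal was 16060 and 25943 in the depleted RNA and 14226 and 16117 at 0 h. STE2 and ASG7 were above background on neither array, whereas MFA1, MFA2, STE6 and BAR1 were above it in both RNAs.

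Of the 36 lists, 3 were called in none of the 5 comparisons, although single members passed. Nucleoporins had medians of -0.01 in nup157Δ (4 lower and 2 higher of 33 [6 and 2]), -0.14 in nup170Δ (13 lower and 2 higher of 33 [13 and 2]), -0.07 in nup188Δ (3 lower and 1 higher of 33 [3 and 1]), 0.03 on depletion (7 higher and 9 lower of 33 [7 and 9]) and -0.06 on reinduction (2 lower and 0 higher of 33 [1 and 0]), with the list alone in square brackets. Alpha-specific genes had medians of -0.06, 0.40 (5 higher and 1 lower of 9 [5 and 1]), 0.03, -0.07 and 0.02, and strain markers of -0.13, -0.16, -0.13, -0.33 and -0.16, in the same order.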
